A study of Mus musculus with 14 samples.

How the data were processed

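RNA from subcutaneous mouse tumours was sequenced in 14 libraries, per the labels: untreated at day 0 (n = 3) and, at day 7 after an intratumoral injection given at a tumour size of about 150 mm3, D5W (n = 3), 2E'/PTX/siNeg (n = 4) and 2E'/PTX/siPD-L1 (n = 4), where PTX is read as paclitaxel. The protocol also lists injections of 2E' and of 2E'/PTX, which are not analysed here. RNA was isolated with a Qiagen RNeasy kit and libraries followed the Illumina TruSeq stranded protocol, per the labels' protocols. Per the submitters' processing notes, reads passed FastQC 0.11.3, STAR, featureCounts and edgeR on GRCm38. The annotation release, the strand setting of the counting and the versions of STAR, featureCounts and edgeR are not given in the sources used here. The authors deposited raw read counts per Ensembl gene, and every value used here starts from these deposited counts; the values are whole numbers. Each of the 14 count columns was matched to its label by name, and 0 were unmatched.

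Of 37409 deposited genes, 3935 had no count in any library. Symbols, positions and transcript features came from GENCODE M21 (GRCm38), which matched 37386 of the gene IDs and left 23 without a symbol. Library totals were 60.2 M to 75.3 M counts at day 0, 73.1 M to 85.9 M with D5W, 68.5 M to 80.2 M with siNeg and 66.7 M to 84.4 M with siPD-L1. The biological coefficient of variation was 16.6%. Spread between replicates was larger than sampling noise in every group, so errors are taken from the replicates.

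Gene tests used R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr by group (17141 genes tested), 1 robust quasi-likelihood fit of all 14 libraries with a coefficient per group, F-tests, and Benjamini-Hochberg adjustment at 0.05. Comparisons were D5W against day 0, siNeg and siPD-L1 each against D5W, siPD-L1 against siNeg, and siNeg and siPD-L1 each against day 0. No pairing was used, since the labels state none for the replicate numbers. The pipeline was tested on simulated data made from these counts, with known genes shifted and a list shifted.

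Named genes in each comparison are Cd274, the 6 highest and the 6 lowest log2 fold changes among genes with adjusted p under 0.05, mean CPM of at least 1 and no overlap of the groups in log2 CPM, and up to 4 members with the smallest p of each list described. Predicted genes, immunoglobulin and T cell receptor segments and pseudogenes were left out of the highest and lowest genes. Some named genes are not reported here. Log2 CPM used a prior count of 2.

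Gene lists of 443 genes in 30 groups covered identity and cell types (melanocyte lineage, intestinal epithelium, T, NK, B and plasma, macrophage, dendritic, neutrophil, fibroblast and matrix, endothelial, skeletal muscle, adipocyte, keratinocyte, erythroid) and pathways (cytotoxic, M1-associated, M2-associated, immune checkpoint, type I interferon, interferon gamma, MHC class I, MHC class II, Toll-like receptor and NF-kB, nucleic acid sensing, mitosis, DNA replication, tubulin, p53, endoplasmic reticulum stress, hypoxia and glycolysis). They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Some lists share genes, so their results are not separate. Type I interferon and nucleic acid sensing share Ddx58, Ifih1, Irf7 and Zbp1. The M1-associated list shares Tnf, Il1b and Il6 with the Toll-like receptor and NF-kB list. The adipocyte list kept 2 tested members, below the minimum of 3, and was not tested; 29 lists were. The list genes Mc1r, Irf8, Gbp4, Myd88, Sting1, Mb21d1, Tubb3 and Ahsp had no match by symbol and are not analysed here.

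Groups, tests, lists, the naming rule and a first set of alternatives were chosen before the data were examined. Those alternatives were DESeq2 size factors in edgeR, library totals only, no low-count filter, CPM above 1 in 3 libraries, DESeq2 1.42.0 with a Wald test, limma voom with sample weights, only the 2 groups compared, replicate number as a block, leaving out each library in turn, and for lists the estimated correlation. Alternatives added after were leaving out D5W replicate 3 and siPD-L1 replicate 1 together, leaving out mitochondrial and ribosomal RNA-like genes (Gm42418, Cmss1, Gm26561, Cdk8, Lars2, Gphn), and removing the trend with transcript GC content and length by offsets. Lists added after were immediate early genes, Nrf2 antioxidant targets and secretory pathway machinery, as was the comparison of both siRNA groups together (n = 8) with D5W. Overlap between comparisons with shared controls was set beside 20 simulations with no effect and the expected n1 × n2 / N. Correlations with Cd274 used 100000 permutations of the libraries.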

Results

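Read counts per gene were analysed for 14 mouse tumour libraries in 4 groups: untreated at day 0 (n = 3), and day 7 after a single intratumoral injection of 5% dextrose in water (D5W, n = 3), of 2E'/paclitaxel with a negative-control siRNA (siNeg, n = 4) or of 2E'/paclitaxel with an siRNA to PD-L1 (siPD-L1, n = 4). 2E' is taken here as the immunoactive polymer of the series title. Totals ran from 60.2 M to 85.9 M counts per library, and 17141 of 37409 genes passed the expression filter. Means are given in CPM (counts per 1 M counts, TMM-scaled) ± SD, and log2 fold changes ± standard error with p-values adjusted over all tested genes by edgeR. The p-values measure the spread between the sequenced samples, and the labels name C57BL/6 mice as their source without stating that each library is a separate mouse.

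Genes of the pigment cell lineage were among the strongest in every group. Over the 14 libraries the median CPM was 7915 for Dct and 5068 for Tyrp1, enzymes of melanin synthesis. It was 3764 for Pmel, a protein of the pigment granule, and 1043 for Mitf, the lineage's transcription factor. Intestinal epithelial genes were near zero, with median CPM of 0.052 for the adhesion gene Epcam, 0.0164 for the transcription factor Cdx1 and 0.019 for the keratin Krt20, while Vil1, Lgals4 and Cdh1 had 3.84, 2.08 and 2.06. The labels name CT26 (a colon carcinoma) as the cell type and B16F10 (a melanoma) in the treatment protocol, and the expressed genes are those of a melanoma. Day 0 libraries stood apart from all day 7 libraries on the first principal component, and D5W replicate 3 lay farthest from them.

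**Figure D1:**
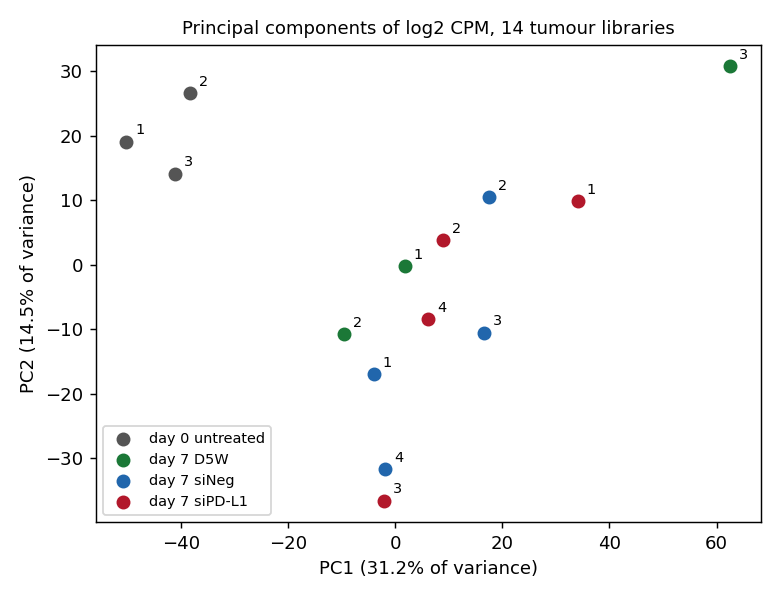
Principal components of log2 CPM for the 14 libraries, coloured by group; the first axis holds 31.2% of the variance and the second 14.5%. The 3 day 0 libraries lie at the low end of the first axis and D5W replicate 3 lies at 62.6.

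Cd274 encodes PD-L1, the ligand by which tumour and myeloid cells restrain T cells, and is the target of the siRNA (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095, GRCm38 with GENCODE M21; it overlaps AC119228.1 on the opposite strand). Its CPM in each library was 11.8, 12.5 and 11.8 at day 0, 14.8, 13.8 and 18.5 with D5W, 17.6, 31.6, 28.8 and 21.6 with siNeg, and 15.8, 16.5, 17.0 and 20.8 with siPD-L1. Group means were 12.006±0.431, 15.7±2.50, 24.9±6.44 and 17.5±2.25. Against day 0, Cd274 rose by 1.05±0.18 with siNeg (adjusted p = 0.00139) and by 0.55±0.17 with siPD-L1 (adjusted p = 0.0366), and differed by 0.39±0.18 with D5W (adjusted p = 0.143). Between the siRNA groups it was 0.50±0.16 log2 lower with siPD-L1, a difference that did not pass (edgeR adjusted p = 0.515; exact permutation p = 0.0571 over 70 assignments). Against D5W the log2 fold change was 0.67±0.17 for siNeg (adjusted p = 0.122, and 0.66 with adjusted p = 0.0108 by DESeq2) and 0.16±0.17 for siPD-L1 (adjusted p = 0.913). The call for siPD-L1 against day 0 was lost with library totals only (0.56), with the GC and length trend removed (0.46) and when any single day 0 library or siPD-L1 replicate 3 or 4 was left out.

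**Figure D2:**
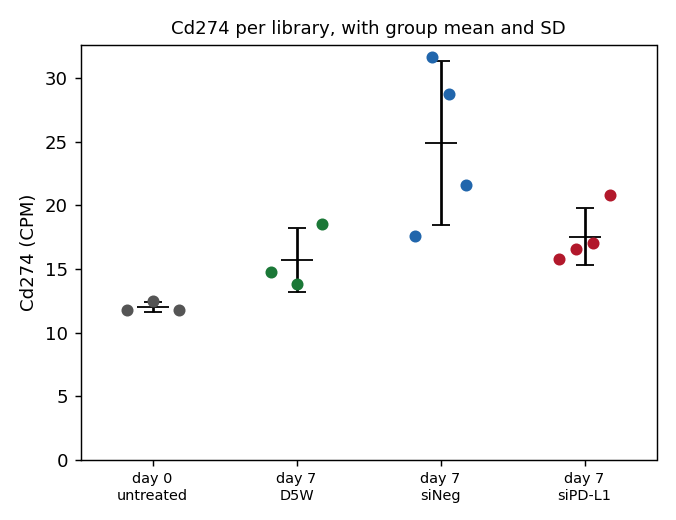
Cd274 CPM in each library (points) with group mean and SD (bars) for day 0, D5W, siNeg and siPD-L1. The siNeg libraries run from 17.6 to 31.6 CPM and the siPD-L1 libraries from 15.8 to 20.8.

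Nr4a2, Cxcl1 and Il6 rose in D5W tumours at day 7 against untreated tumours at day 0. This comparison asks what 7 days of growth with the vehicle injection changed. In every comparison with day 0, however, day cannot be told apart from tumour collection. A trend with transcript GC content and length also differs between the days. Nr4a2, an orphan nuclear receptor induced within minutes of many stimuli, averaged 152±56 CPM against 5.70±0.37 (log2 fold change 4.74±0.43, adjusted p = 4.7e-05, n = 3 and 3). The neutrophil-attracting chemokine Cxcl1 rose by 5.42±0.77 (9.12±6.3 against 0.21±0.027 CPM, adjusted p = 0.00074). The cytokine Il6 rose by 5.06±0.76 (2.71±1.7 against 0.0799±0.034, adjusted p = 0.00086). The pattern-recognition protein Ptx3 (5.85±1.29), the hyaluronan synthase Has1 (4.83±1.01) and the regulatory cytokine Il10 (4.69±0.72) completed the 6 largest rises under the naming rule, with adjusted p = 0.0095, 0.0065 and 0.00099.

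Toll-like receptor and NF-kB genes rose in 14 of 23 tested members (15 adjusted over the list alone, median 1.41), among them the alarmin Il1a (4.46±0.54, 6.78±2.6 against 0.311±0.11 CPM), Tnf (3.99±0.55) and the NF-kB cofactor Nfkbiz (2.07±0.22, 44±15 against 10.5±1.8 CPM). M1-associated macrophage genes rose in 5 of 10 (6 adjusted over the list alone, median 1.73), with the prostaglandin enzyme Ptgs2 at 3.27±0.51 and Il1b at 2.65±0.66. Interferon gamma response genes rose in 2 of 14, the feedback inhibitor Socs3 (1.70±0.34) and the chemokine Cxcl10 (0.79±0.23; 2 adjusted over the list alone, median 0.68). Endothelial genes rose in 5 of 13 (6 adjusted over the list alone, median 0.88), including Vwf (0.74±0.17) and the VEGF receptor Kdr (1.49±0.38). Fibroblast and matrix genes rose in 4 of 20 (12 adjusted over the list alone, median 1.15), including Fn1 (0.68±0.17) and Col6a3 (1.41±0.45). These 5 lists passed camera upward with adjusted p = 0.983 with an estimated correlation for each.

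Hypoxia and glycolysis genes fell in 9 of 18 (12 adjusted over the list alone, median -0.40). The vasodilator peptide Adm fell from 54±4.3 to 22.5±4.5 CPM (-1.26±0.13, adjusted p = 4.6e-05), and other members that fell were Ankrd37 (-1.59±0.20), the mitophagy gene Bnip3 (-0.53±0.14) and Vegfa, the main blood vessel growth factor (-0.38±0.10, 255±29 against 332±23 CPM). Erythroid genes fell in 1 of 7 (1 adjusted over the list alone, median -2.73). Both lists passed camera downward with adjusted p = 0.983 with an estimated correlation. The mTOR inhibitor Ddit4, also induced by low oxygen, fell from 178±12 to 60.1±17 CPM (-1.56±0.18, adjusted p = 0.00013), as did Inka1 (-1.67±0.20) and the lipolysis inhibitor G0s2 (-1.36±0.23). The lowest named genes were mt-Co2 (-4.85±1.09) and mt-Atp8 (-2.92±0.85), which are uncertain because mitochondrial genes have nuclear copies. Endoplasmic reticulum stress genes went both ways, 2 up and 4 down of 14, with Atf3 at 1.27±0.18 and the pro-death factor Ddit3 at -0.95±0.15 (34.6±5.0 against 66.8±11 CPM). Mitf rose by 1.09±0.12 (1155±130 against 541±20 CPM, adjusted p = 6.6e-05) while Mlana, one of its pigment targets, fell by 0.53±0.10 (376±61 against 543±23 CPM).

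Other lists did not pass. Of the 17141 tested genes 2030 rose and 1661 fell in this comparison, 21.5% in all. Member counts near these shares, also those given above, do not by themselves set a list apart. Type I interferon genes had 0 of 20 members called (median 0.43), T cell genes 0 of 18 (median 0.64), NK cell genes 0 of 6, dendritic cell genes 0 of 11, MHC class II genes 0 of 11, keratinocyte genes 0 of 4 and intestinal genes 0 of 3. Members rose for p53 response (3 of 18, with Plk2 at 2.42±0.20), MHC class I (2 of 16, with its activator Nlrc5 at 1.53±0.29), mitosis (3 of 22, with Mki67 at 0.58±0.13 and 1 fall, Birc5 at -0.34±0.10) and neutrophil genes (2 of 9). Single members rose for immune checkpoint (1 of 12, Ctla4 at 2.11±0.55), cytotoxic (1 of 13), M2-associated (1 of 11), tubulin (1 of 12, Tubb2a at 0.68±0.13) and macrophage (1 of 15, Cd14 at 2.30±0.54). For macrophage genes the median was -0.02 while the mean was 0.21. B and plasma cell (Ms4a1 at -1.85±0.48) and DNA replication genes (Gins2 at -0.42±0.12) each had 1 fall. Nucleic acid sensing had 3 falls of 14 with a median of 0.27, and melanocyte genes 1 rise and 1 fall of 14. Skeletal muscle had 2 rises and 1 fall of 15 with a median of -0.41, and the adipocyte genes Lipe and Fabp4 had -0.27±0.21 and 0.49±0.44.

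By edgeR 3691 genes changed, 2030 higher and 1661 lower, of which 519 rose and 106 fell at least 2-fold. Before adjustment 6318 had p under 0.05. In 43.8% of genes the groups did not overlap, where 10% is the chance share. Leaving out 1 library moved the count from 1350 (without day 0 replicate 1) to 4031 (without D5W replicate 2), with 2036 without D5W replicate 3. With library totals only the count was 2361, of which 83.9% were higher (55.0% with TMM), and with mitochondrial and ribosomal RNA-like genes left out 1877 were higher and 1997 lower. The interferon gamma list did not pass without day 0 replicate 2 or D5W replicate 1 or 3, with voom or with the replicate block. The erythroid list did not pass without day 0 replicate 2 or D5W replicate 2 or 3, with voom, with CPM above 1 or without mitochondrial and ribosomal RNA-like genes. The fibroblast list, at library means of 4.31, 3.05 and 4.67 log2 CPM for D5W replicates 1, 2 and 3, was lost without replicate 1 or 3 and with voom, the calls for Mki67 and Cenpf with the GC and length trend removed, and mt-Co2 without D5W replicate 3.

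Vegfa, St3gal1 and Map3k12 rose and Cdsn, Acox2 and Avil fell when siNeg tumours were compared with D5W tumours, which asks what polymer, paclitaxel and a negative siRNA changed at the same day. Vegfa averaged 367±37 CPM against 255±29 (0.53±0.09, adjusted p = 0.039, n = 4 and 3). The sialyltransferase St3gal1 had 127±29 against 66.1±7.4 (0.94±0.16, adjusted p = 0.047) and the stress kinase Map3k12 14.2±0.50 against 9.53±0.98 (0.58±0.09, adjusted p = 0.032). Cdsn, a cell adhesion protein best known from cornified skin (ENSMUSG00000039518, chromosome 17, 35552128 to 35557180), fell by 2.54±0.38 (2.12±1.2 against 12.4±2.1 CPM, adjusted p = 0.032). Falls also met the test for the peroxisomal oxidase Acox2 (-2.42±0.38), the actin-binding protein Avil (-2.39±0.40), the endoplasmic reticulum exit site protein Sec16b (-2.14±0.33), the sulfate donor enzyme Papss2 (-1.85±0.27) and Rcn3, a calcium-binding protein of the secretory pathway (-1.09±0.17, 15.9±4.4 against 33.9±1.1 CPM).

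Of the type I interferon genes 0 of 20 passed over all genes and 12 were higher adjusted over the list alone (median 0.75, 19 above 0). Oas1a, an antiviral RNA sensor, had 14.1±2.8 against 8.42±1.0 CPM (0.75±0.13, adjusted p = 0.050). Irf7, the amplifier of the response, had 10.4±5.3 against 3.86±1.0 (1.43±0.36, adjusted p = 0.12). Hypoxia genes had 1 of 18 called and 16 higher adjusted over the list alone (median 0.35, 18 above 0), with Ankrd37 at 0.90±0.19 (adjusted p = 0.077). Fibroblast and matrix genes had 0 of 20 called and adjusted over the list alone 13 lower and 1 higher (median -1.19), with Lox, which crosslinks collagen, at -2.63±0.64 and Col3a1 at -2.82±0.82 (30.6±15 against 216±190 CPM, adjusted p = 0.18). These 3 lists and nucleic acid sensing (0 of 14, 4 adjusted over the list alone, median 0.21) passed camera in the direction of their medians, each with adjusted p = 0.642 with an estimated correlation. Endothelial genes passed downward (0 of 13, 0 adjusted over the list alone, median -0.77, adjusted p = 0.703 with an estimated correlation). Hypoxia list means were 8.61 log2 CPM at day 0, 8.13 with D5W and 8.54 with siNeg, and fibroblast means 3.13, 4.01 and 2.97. For both lists D5W lay farther from day 0 than siNeg did. The D5W libraries also varied, from 7.78 to 8.34 for hypoxia genes and from 3.05 to 4.67 for fibroblast genes. These differences may therefore come from the treatment or from the D5W libraries, which these values cannot tell apart.

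MHC class I genes (0 of 16; adjusted over the list alone 5 higher and 2 lower; median 0.42) included the peptide-loading protein Tapbp at 0.68±0.14 (adjusted p = 0.077) and B2m at 0.51±0.17 (418±80 against 295±55 CPM). Interferon gamma genes (0 of 14, 3 adjusted over the list alone, median 0.50) had Irgm1 at 0.72±0.19. Cytotoxic genes (0 of 13, 3 adjusted over the list alone, median 1.10) had Gzma at 2.57±0.58 (0.607±0.36 against 0.103±0.089 CPM), and NK cell genes had a median of 1.03. Lower lists were endoplasmic reticulum stress (4 adjusted over the list alone, median -0.14, with the chaperone Hspa5 at -0.42±0.12) and mitosis (median -0.11, 3 of 22 above 0). So were DNA replication (median -0.06), M1-associated (1 adjusted over the list alone, median -0.57) and M2-associated genes (1 adjusted over the list alone, median -0.72), and melanocyte genes passed upward (median 0.14). All 10 of these camera calls had adjusted p = 0.705 with an estimated correlation. Over 18 settings the melanocyte call was lost in 10, the M1-associated call in 9 and the M2-associated call in 10, with adjusted p at the preset correlation up to 0.720, 0.743 and 0.351. The DNA replication call was lost in 6 of 18 settings (adjusted p up to 0.428) and the NK cell call in 5 of 17 (up to 0.334).

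By edgeR 18 genes changed, 4 higher and 14 lower, of which 1 and 9 changed at least 2-fold. Before adjustment 2562 had p under 0.05, and DESeq2 called 446 and voom 310; 14.3% of genes did not overlap (chance 5.71%). Without siNeg replicate 2 the count was 0, without siNeg replicate 1 it was 4, and without D5W replicate 2 it was 123 (10 higher and 113 lower). Without D5W replicate 3 it was 17, with 12 higher and 5 lower, and 5 of the 18 genes were among them. Each of the 9 genes named first was lost without siNeg replicate 1 and without siNeg replicate 2. In a simulation of this comparison 37.3% of genes changed 1.5-fold, 67.2% of those changed 2-fold and 87.9% of those changed 4-fold were found. It also called 8 unchanged genes. The simulation planted many changes, which eases the adjusted cutoff, and drew genes independently, so the real comparison may find fewer.

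By edgeR, each of the 5 genes that changed between siPD-L1 and D5W tumours fell, in the comparison that asks what the treatment with PD-L1 siRNA changed at the same day. Kdelr3, a receptor that returns chaperones to the endoplasmic reticulum (ENSMUSG00000010830, chromosome 15, 79516411 to 79527739, overlapping Ddx17 on the opposite strand), averaged 6.28±0.58 CPM against 12.8±0.40 (-1.02±0.14, adjusted p = 0.0205, n = 4 and 3). Sec24d, a coat protein of vesicles leaving the endoplasmic reticulum, fell by 0.52±0.08 (60.3±3.2 against 86.3±5.8 CPM, adjusted p = 0.042), and Prrc1, which works with that coat, by 0.38±0.06 (adjusted p = 0.034). The methyltransferase Nnmt fell by 1.08±0.16 (3.23±0.72 against 6.82±0.39 CPM, adjusted p = 0.034) and the branched-chain amino acid enzyme Bcat1 by 0.58±0.07 (72.4±6.1 against 108±6.8 CPM, adjusted p = 0.020).

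Endoplasmic reticulum stress genes passed camera downward (0 of 14, 8 adjusted over the list alone, median -0.30, adjusted p = 0.245 with an estimated correlation). The asparagine synthetase Asns had -0.48±0.10 (167±25 against 232±26 CPM), Trib3 -0.58±0.15, Herpud1 -0.43±0.11 and Dnajb9 -0.65±0.19. Hypoxia genes passed upward (0 of 18, 8 adjusted over the list alone, median 0.25, 18 of 18 above 0, adjusted p = 0.245 with an estimated correlation). Adm had 0.63±0.12 (34.9±3.3 against 22.5±4.5 CPM) and Vegfa 0.45±0.09 (350±9.4 against 255±29 CPM, adjusted p = 0.074). Fibroblast genes passed downward (0 of 20, 0 adjusted over the list alone, median -0.62, adjusted p = 0.755 with an estimated correlation). The hypoxia and fibroblast list means with siPD-L1 (8.47 and 3.26 log2 CPM) lay nearer day 0 (8.61 and 3.13) than D5W did (8.13 and 4.01). Macrophage (1 adjusted over the list alone, median -0.38), Toll-like receptor and NF-kB (0 of 23, median -0.28) and M1-associated genes (1 adjusted over the list alone, median -0.36) passed downward. Passing upward were cytotoxic (median 0.35), skeletal muscle (0.27), type I interferon (0.23), erythroid (0.89) and neutrophil genes (0.58), and all 8 had adjusted p = 0.946 with an estimated correlation. Of 18 settings (17 for cytotoxic genes) the call was lost in 10 for neutrophil, 9 for erythroid, 8 for M1-associated, 7 for cytotoxic, 6 for type I interferon, 5 for macrophage and 4 for Toll-like receptor and NF-kB genes. For skeletal muscle it was lost in 7 and turned in 1, and over these lists the adjusted p at the preset correlation reached 0.915. Single members were Il6 at -1.83±0.54 (adjusted p = 0.30), Gzma at 1.74±0.59 (adjusted p = 0.39) and Irf7 at 0.72±0.36 (adjusted p = 0.66).

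By edgeR 5 genes changed; before adjustment 1375 had p under 0.05, DESeq2 called 177 (42 higher and 135 lower) and voom 22 (11 higher and 11 lower), and 5.74% of genes did not overlap (chance 5.71%). Without D5W replicate 3 the count was 10, with 5 higher and 5 lower, and without siPD-L1 replicate 1 or 2 it was 0. Without replicate 3 it was 1, a higher gene that is not among the 5, and without replicate 4 it was 6, with 4 of the 5 among them. Gm42418, which lies in a ribosomal RNA repeat, took 9.71% of the counts of siPD-L1 replicate 1 (95% Wilson interval 9.701 to 9.714%, counting error only) and 0.275 to 0.576% of the other 3.

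Both siRNA groups were compared with the same D5W libraries. Their fold changes correlated with r = 0.68 over all genes, against 0.57 in simulations with no effect; the covariance was 0.0959 against 0.0491. They shared 0 higher and 2 lower calls, where 0.00408 would be expected for lower genes. The 3 D5W libraries are too few to split, so part of the excess may come from the shared controls.

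No gene changed between siPD-L1 and siNeg tumours by edgeR (0, n = 4 and 4), the comparison that holds polymer and paclitaxel the same and asks what the PD-L1 siRNA changed. B2m, the light chain of MHC class I, had -0.71±0.15 (256±38 against 418±80 CPM, adjusted p = 0.42), the peptide transporter Tap2 -0.67±0.17 (adjusted p = 0.46) and Mitf 0.52±0.10 (1340±210 against 934±58 CPM, adjusted p = 0.42). Interferon-induced Isg15 had 3.88±0.26 against 6.03±2.1 CPM (-0.64±0.19, adjusted p = 0.50).

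MHC class I genes passed camera downward (0 of 16, 7 adjusted over the list alone, median -0.45), and so did type I interferon (0 of 20, 2 adjusted over the list alone, median -0.52, 0 of 20 above 0), both with adjusted p = 0.616 with an estimated correlation. The same value applies to endoplasmic reticulum stress (3 adjusted over the list alone, median -0.14, with Trib3 at -0.55±0.14) and nucleic acid sensing genes (median -0.14), also downward. Mitosis (median 0.14, 21 of 22 above 0, with Mki67 at 0.28±0.11 and Kif2c at 0.20±0.07) and endothelial genes (median 0.49, with the junction gene Cldn5 at 1.07±0.41) passed upward, also with adjusted p = 0.616 with an estimated correlation. Interferon gamma genes passed downward (median -0.26, 0 of 14 above 0) and erythroid (median 1.77) and p53 genes (1 adjusted over the list alone, median 0.13, with Ccng1 at 0.33±0.09) upward, with adjusted p = 0.672 with an estimated correlation. Cytotoxic (median -0.60, with Nkg7 at -1.26±0.55) and T cell genes (median -0.39) passed downward and DNA replication genes (median 0.08) upward, with adjusted p = 0.807 with an estimated correlation. The p53 and T cell calls were each lost in 8 of 19 settings, DNA replication in 6 of 19 and cytotoxic in 6 of 18.

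The smallest adjusted p was 0.420, and before adjustment 1471 genes had p under 0.05. DESeq2 called 58 and voom 3, and 5.74% of genes did not overlap (chance 2.86%). In a simulation of this comparison 53.7% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 92.4% of those changed 4-fold were found. It also called 16 unchanged genes. The simulation planted many changes, which eases the adjusted cutoff, and drew genes independently. The real comparison may thus find fewer, and its 0 calls do not exclude changes of these sizes. Leaving out siPD-L1 replicate 4 gave 1 gene and leaving out any other library gave 0.

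Klf4, Sik1 and Slfn4 rose in siNeg tumours against day 0, the control named by the series design. Klf4, a stimulus-induced transcription factor, averaged 364±46 CPM against 27.9±1.3 (3.71±0.23, adjusted p = 4.9e-07, n = 4 and 3). The kinase Sik1 had 358±48 against 28.7±2.8 (3.64±0.28, adjusted p = 3.5e-06) and the interferon-induced Slfn4 9.27±6.2 against 0.748±0.36 (3.66±0.75, adjusted p = 0.0063). Atn1 (3.77±0.46), Nr4a2 (3.58±0.40) and Il1a (3.56±0.52) were the other largest rises. The stress hormone Fgf21 fell from 10.4±3.3 to 1.22±0.82 CPM (-3.08±0.45, adjusted p = 0.00072), with Cdsn (-3.05±0.38), Acox2 (-2.88±0.38), Otog (-2.83±0.52), Avil (-2.52±0.41) and mt-Nd4l (-2.76±0.63, uncertain for its nuclear copies).

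Type I interferon genes rose in 15 of 20 (17 adjusted over the list alone, median 1.29), among them Irf7 (1.87±0.37, 10.4±5.3 against 2.85±0.17 CPM), Usp18 (1.69±0.32) and Oas1a (0.86±0.14). Interferon gamma genes rose in 8 of 14 (11 adjusted over the list alone, median 1.04), with Socs3 at 2.23±0.33 and Irgm2 at 1.34±0.22. Toll-like receptor and NF-kB genes rose in 13 of 23 (14 adjusted over the list alone, median 1.22), with Tnf at 3.12±0.52. Nucleic acid sensing genes rose in 6 of 14 with 1 fall (8 and 1 adjusted over the list alone, median 0.49), with the RNA sensor gene Ddx58 at 0.98±0.21. These 4 had adjusted p = 0.694 with an estimated correlation. MHC class I genes rose in 11 of 16 and fell in 2 (11 and 2 adjusted over the list alone, median 0.68), with B2m at 0.90±0.17 (418±80 against 225±34 CPM) and Nlrc5 at 1.74±0.28. Cytotoxic genes rose in 6 of 13 (8 adjusted over the list alone, median 2.19), with Gzmb at 3.29±0.74 (1.95±1.4 against 0.198±0.021 CPM). M1-associated genes rose in 4 of 10 (4 adjusted over the list alone, median 1.59). Endoplasmic reticulum stress genes fell in 7 of 14 and rose in 1 (8 and 1 adjusted over the list alone, median -0.27), with the disulfide enzyme Pdia4 at -0.64±0.11. Erythroid genes fell in 1 of 7 (7 adjusted over the list alone, median -3.39). These 5 lists had adjusted p = 0.729 with an estimated correlation.

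T cell genes rose in 2 of 18 (2 adjusted over the list alone, median 1.10), Icos (2.46±0.64) and Cd8a (1.92±0.55, 0.777±0.44 against 0.205±0.036 CPM), with adjusted p = 0.839 with an estimated correlation. NK cell genes rose in 1 of 6, Il2rb (2.20±0.58; 3 adjusted over the list alone, median 1.65), and DNA replication genes fell in 3 of 18 (3 adjusted over the list alone, median -0.15), both with adjusted p = 0.815 with an estimated correlation. Mitosis genes fell in 5 of 22 and rose in 1 (7 and 1 adjusted over the list alone, median -0.19), with adjusted p = 0.856 with an estimated correlation. The mitosis call was lost in 9 of 18 settings, NK cell in 7 of 17 and T cell in 6 of 18. The checkpoint receptor Ctla4 rose by 3.06±0.54, Mitf by 0.79±0.11 and Fn1 by 1.09±0.17, and the muscle filament gene Des fell by 1.07±0.13.

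By edgeR 3158 genes (18.4% of those tested) changed, 1802 higher and 1356 lower, of which 428 rose and 133 fell at least 2-fold. Before adjustment 5613 had p under 0.05, and 41.7% of genes did not overlap (chance 5.71%). With library totals only 1774 genes changed, 71.1% of them higher (57.1% with TMM), and without day 0 replicate 1 the count was 1281. With mitochondrial and ribosomal RNA-like genes left out the balance turned to 1549 higher and 1669 lower. Kif2c and Tyms, which fell by 0.35±0.08 and 0.33±0.08, were not called with library totals only.

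Nr4a2, Sik1 and Klf4 also rose in siPD-L1 tumours against day 0. Nr4a2 averaged 92±36 CPM against 5.70±0.37 (4.01±0.41, adjusted p = 0.00011, n = 4 and 3). Sik1 had 432±160 against 28.7±2.8 (3.91±0.28, adjusted p = 2.5e-06) and Klf4 344±98 against 27.9±1.3 (3.63±0.23, adjusted p = 5.5e-07). Cxcl1 (3.83±0.73), Il1a (3.53±0.52) and the ribosomal RNA gene n-R5-8s1 (3.96±0.81) were the other largest rises. n-R5-8s1 had 10.3 CPM in replicate 1 and 0.981 to 3.98 in the other 3, and 2.96 log2 without that library (adjusted p = 0.00553). Fgf21 fell by 2.87±0.45, Cdsn by 2.83±0.38 (2.49±0.29 against 17.8±8.8 CPM), the aldo-keto reductase Akr1b7 by 2.56±0.35, Acox2 by 2.50±0.37, Otog by 2.47±0.51 and Avil by 2.42±0.40.

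Toll-like receptor and NF-kB genes rose in 11 of 23 (adjusted over the list alone 13 up and 1 down, median 1.18), with Nfkbiz at 2.13±0.21. M1-associated genes rose in 4 of 10 (4 adjusted over the list alone, median 1.10), with Ptgs2 at 2.77±0.49. Interferon gamma genes rose in 4 of 14 (7 adjusted over the list alone, median 0.70), with Gbp2 at 1.28±0.41. Type I interferon genes rose in 6 of 20 (11 adjusted over the list alone, median 0.71), with Mx1 at 1.15±0.37 and Irf7 at 1.16±0.37. Cytotoxic genes rose in 4 of 13 (adjusted over the list alone 6 up and 1 down, median 1.62), with Gzmb at 2.69±0.73. Endothelial genes rose in 3 and fell in 1 of 13 (4 and 1 adjusted over the list alone, median 0.78), with Kdr at 1.22±0.36. Endoplasmic reticulum stress genes fell in 8 of 14 and rose in 1 (10 and 1 adjusted over the list alone, median -0.39), with Trib3 at -1.20±0.15 (57.5±15 against 132±13 CPM), Sdf2l1 at -0.82±0.12 and Atf4 at -0.56±0.09. All 7 lists had adjusted p = 0.949 with an estimated correlation. The endothelial call was lost in 7 of 18 settings and the cytotoxic call in 6 of 17. Mitf rose by 1.31±0.11 (1340±210 against 541±20 CPM), Plk2 by 2.73±0.20, Ctla4 by 2.71±0.53 and Mki67 by 0.59±0.12. The growth factor gene Tgfb1 fell by 0.61±0.14 and the macrophage lysozyme Lyz2 by 0.97±0.32.

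By edgeR 3756 genes (21.9% of those tested) changed, 1968 higher and 1788 lower, of which 363 rose and 151 fell at least 2-fold. Before adjustment 6183 had p under 0.05, and 35.0% of genes did not overlap (chance 5.71%). With library totals only 2077 genes changed and without day 0 replicate 1 the count was 1653, and Mki67 was lost with the GC and length trend removed. With mitochondrial and ribosomal RNA-like genes left out the balance turned to 1703 higher and 2119 lower.

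In all 3 day 7 groups against day 0, 1119 genes were higher and 704 lower. With the GC and length trend removed, 1831 of the 3691 genes called for D5W against day 0 were called again. For siNeg 1900 of 3158 were, and for siPD-L1 1855 of 3756. The genes common to the 3 groups were not counted again under that setting. Pairs of these comparisons share the day 0 libraries: their fold changes correlated with r = 0.77 (D5W and siNeg), 0.82 (D5W and siPD-L1) and 0.85 (siNeg and siPD-L1), against 0.54, 0.54 and 0.59 simulated with no effect. The covariances were 0.261, 0.285 and 0.264 against 0.0507, 0.0506 and 0.0506. Shared higher calls were 1232, 1452 and 1346, where 213, 233 and 207 would be expected for independent comparisons. Shared lower calls were 790, 1159 and 970, where 131, 173 and 141 would be expected in the same way. Comparisons that share the day 0 libraries are not independent. The excess therefore cannot tell a change common to the day 7 groups from a deviation of the day 0 libraries.

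Gene expression also followed transcript features that differed between the days. Over 12292 genes, the correlation of a library's deviation with log2 transcript length was -0.38, -0.39 and -0.23 at day 0, 0.09 to 0.25 with D5W, -0.13 to 0.13 with siNeg and -0.06 to 0.21 with siPD-L1. With GC content it was 0.20 to 0.24 at day 0 and as low as -0.47 in siPD-L1 replicate 3. The 74 ribosomal protein genes had library means of 8.21 to 8.56 log2 CPM at day 0 and 7.45 to 8.11 at day 7. Mitochondrial transcripts took 8.63±6.10% of counts at day 0, 3.52±0.831% with D5W, 5.31±1.69% with siNeg and 5.28±0.321% with siPD-L1. The day 0 replicates 1, 2 and 3 had 7.43, 15.2 and 3.23%, so replicate 2 raised the day 0 mean and the other day 0 values lay within the day 7 range.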

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

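Library values that stood apart from the other libraries of their group were looked for in 118 groups of values; 11 did, where about 1 in 20, or 5.9, are expected by chance. The largest was Gm42418 in siPD-L1 replicate 1, 9.71% of counts against 0.275 to 0.576% in the other 3. Other siPD-L1 values far from the rest were the melanocyte list mean of replicate 2 (9.04 log2 CPM against 9.32 to 9.37), the T cell list of replicate 3 (-1.91 against -1.06 to -0.94), the MHC class I list of replicate 3 (4.51 against 4.86 to 4.92), Otog in replicate 2 (-1.85 against 0.07 to 0.34) and mt-Nd4l in replicate 4 (2.35 against 0.04 to 0.40). In siNeg replicate 2 the intestinal list was 1.33 against 1.20 to 1.22, the B and plasma cell list -1.30 against -2.20 to -2.12 and the neutrophil list 1.19 against -0.15 to -0.01. Map3k12 in siNeg replicate 4 was 3.91 against 3.799 to 3.814, and mt-Nd4l in siNeg replicate 3 was -1.12 against 0.06 to 0.30. The critical value was that for 4 samples, and every flagged value was in siNeg or siPD-L1. The search therefore does not show that day 0 and D5W libraries lack such values.

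The tests of host cells and of tumour collection in this part were chosen after the results were seen, and the test of the GC and length trend before. Immediate early genes were higher at day 7 than at day 0, which could reflect signalling in the tumour, more host cells that express them, the way the tumours were collected, or the trend with transcript GC content and length. More macrophages, fibroblasts or endothelial cells do not account for the rise with siNeg and siPD-L1: it exceeded the rise of each of these cell lists by at least 0.897 (endothelial genes, standard error 0.278). Other host cells are not left out. With each of 11 cell list means subtracted, siNeg or siPD-L1 libraries overlapped day 0 for NK cell, neutrophil, keratinocyte and erythroid genes. They did not overlap for the other lists. For D5W the smallest excess was 0.805 over fibroblast genes (standard error 0.515), so a rise in stromal cells cannot be told apart from signalling. The lowest day 7 library lay 1.22 log2 CPM above the highest day 0 library, and 1.44 with the GC and length trend removed, which leaves out that trend but not collection, since day and collection cannot be told apart.

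Both tests in this part were chosen before the results were seen. Cd274 was lower with siPD-L1 than with siNeg, which could come from the siRNA or from a different interferon response in the tumours. The difference in log2 CPM was -0.47 (exact p = 0.0571 over 70 assignments, of which the smallest possible is 0.0286) and -0.33 with the interferon gamma list mean as covariate (95% interval -0.70 to 0.05, exact p = 0.143). With 68.7% of the difference left, the 2 explanations cannot be told apart.

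In this part the lists, the test without siPD-L1 replicate 1 and the tests of list means with a stromal covariate were chosen after the results were seen, and the test of the called genes with that covariate before (its jackknife error after). Secretory and antioxidant genes were lower in both siRNA groups than with D5W, which could reflect the treatment, fewer stromal cells, or the ribosomal RNA-like reads of siPD-L1 replicate 1. Without siPD-L1 replicate 1 a new test of all genes called 117 lower, against 55 with it, which leaves that library out as the whole source. With the fibroblast list mean as covariate the secretory list mean differed by -0.23 log2 CPM (standard error 0.0304, -0.22 without it). The Nrf2 list mean differed by -0.24 (standard error 0.0436, -0.28 without it). This leaves out fibroblasts, as that list tracks them, as the whole source of these 2 falls, though not of a part. Macrophage and endothelial list means were also lower with siNeg (2.83 and 1.03) and siPD-L1 (2.69 and 1.54) than with D5W (3.13 and 1.73). They were not used as covariates, so other host cells are not left out. Over the 55 genes the median log2 fold change went from -0.94 to -0.74 with the covariate, 79.5% of it (jackknife standard error over libraries 15.2). With the covariate 2 of all tested genes were called, and 1 of the 55 was among them. The fold shrank and the median error of single genes grew from 0.168 to 0.205. For the 55 genes a stromal share thus cannot be told apart from the treatment. Without D5W replicate 3, 1 gene was called and the median was -0.78.

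Other splits of the same libraries were tested, for D5W against day 0 and siNeg against D5W after the results were seen. For siNeg against day 0 (3158, highest other split 1) only the real split was as large, 1 of 35. The same held for siPD-L1 against day 0 (3756, highest other 1965). A share of 1 of 35 is the smallest these splits can give. Chance cannot be excluded as the source of the counts for siNeg against D5W (18, highest other 245, 2 of 35). Nor can it for siPD-L1 against D5W (5, highest other 1847, 5 of 35). For siPD-L1 against siNeg (0, highest other 1) the splits decide nothing, since all 35 of 35 must reach a count of 0. D5W against day 0 has too few splits (10, with 1 as large and 0 in the highest other). For both siRNA groups together against D5W, 3 of 100 splits, drawn from 165, were as large (61, highest other 2983). That comparison was added after the results were seen, so this share cannot exclude chance. Its count fell to 1 without D5W replicate 3. The splits with 1847 and 2983 genes set siPD-L1 replicates 1 and 3 with D5W replicate 3, so the day 7 samples have a structure that the groups do not follow. The split with 1965 kept the day 0 libraries together and added siPD-L1 replicate 2, so it largely follows the days.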

How the results depend on the processing

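Counts of changed genes moved with the settings, and the cause was not tested. D5W against day 0: 2361 with library totals, 2320 with no filter, 2237 with only the 2 groups, 2445 with the GC and length trend removed, 2360 without D5W replicate 3 and siPD-L1 replicate 1; lists 4 with voom and 4 without those 2 libraries. siNeg against D5W: 76 with no filter, 29 with CPM above 1, 5 with the replicate block, 446 with DESeq2, 310 with voom, 1 with only the 2 groups, 36 with the trend removed and 5 without the 2 libraries; Cd274 0.66 with DESeq2. siPD-L1 against D5W: 60 with library totals, 39 with no filter, 17 with CPM above 1, 0 with the block, 177 with DESeq2, 22 with voom, 1 with only the 2 groups, 13 without mitochondrial and ribosomal RNA-like genes and 8 without the 2 libraries; lists 7 with the trend removed. siPD-L1 against siNeg: 1 with the block, 58 with DESeq2, 3 with voom and 1 without the 2 libraries. siNeg against day 0: 1774 with library totals, 2038 with no filter, 6890 with voom and 5953 with only the 2 groups. With the trend removed that count was 2456. siPD-L1 against day 0: 2077 with library totals and 2466 with the trend removed; Cd274 0.56 with library totals, 0.53 with the block and 0.46 with the trend removed; lists 11 with no filter and 11 with only the 2 groups. With an estimated correlation 0 of the 29 lists fixed at the start passed in any comparison. Direction turned for Ttn in D5W against day 0 (-0.17 with the trend removed) and for the skeletal muscle list in siPD-L1 against D5W (adjusted p = 0.822 with CPM above 1). Leaving out 1 library gave, for genes, Cd274 and lists in turn: 1350 to 4031, 0.25 to 0.47 and 4 to 8 for D5W against day 0; 0 to 123, 0.53 to 0.80 and 9 to 16 for siNeg against D5W; 0 to 10, 0.07 to 0.30 and 7 to 12 for siPD-L1 against D5W; 0 to 1, -0.64 to -0.37 and 5 to 18 for siPD-L1 against siNeg. Against day 0 it gave 1281 to 2719, 0.92 to 1.17 and 9 to 14 for siNeg, and 1653 to 4107, 0.45 to 0.59 (adjusted p up to 0.119 without day 0 replicate 1) and 5 to 8 for siPD-L1. Libraries with the same replicate number were no more alike (median r = -0.014 over 19 pairs) than others (-0.00 over 54 pairs), so the numbers do not pair the groups.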

Other observations

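Immediate early genes, the first wave switched on by growth factors and stress, rose at day 7 in every group against day 0: 21 of 24 with D5W (adjusted p = 0.000447 with an estimated correlation), 21 with siNeg (adjusted p = 0.000109) and 20 with siPD-L1 (adjusted p = 0.000665). Fosb rose by 3.35±0.22, 3.45±0.22 and 3.09±0.21, Btg2 by 2.76±0.21, 2.63±0.20 and 2.72±0.21, Egr2 by 2.71±0.24, 2.91±0.24 and 2.49±0.24 and Jun by 1.47±0.16, 2.00±0.15 and 1.80±0.15. The list mean was 4.75 to 4.82 log2 CPM in the day 0 libraries and 6.04 to 6.66 in the day 7 libraries. This list was added after the results were seen, and its p-values were adjusted over the added lists alone. They therefore do not count as a separate test of the rise.

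Genes of the secretory pathway and of the Nrf2 antioxidant response were lower when both siRNA groups (n = 8) were set against D5W (n = 3), with 61 genes changed, 6 higher and 55 lower. The comparison and both lists were added after the results were seen. Secretory machinery fell in 6 of 26 genes (23 below 0, adjusted p = 0.000286 with an estimated correlation). Those were Kdelr3 (-1.05±0.12, 6.17±0.89 against 12.8±0.40 CPM), Sec24d (-0.49±0.07), the translocon subunit Sec61a1 (-0.33±0.06), the glycosylation enzyme Stt3a (-0.35±0.06), Sec23a (-0.36±0.07) and Sec24a (-0.33±0.06). Nrf2 targets fell in 3 of 20 (15 below 0, adjusted p = 0.000996 with an estimated correlation). Those were the haem oxygenase Hmox1 (-0.68±0.10, 141±18 against 227±14 CPM), Srxn1 (-0.61±0.12) and the glutathione synthesis gene Gclm (-0.48±0.10). Library means of the secretory list were 7.08 to 7.13 log2 CPM with D5W and 6.86 to 6.96 in the treated libraries, and of the Nrf2 list 6.92 to 6.96 and 6.59 to 6.78. Vegfa (0.49±0.08), Ankrd37 (0.84±0.17) and Map3k12 (0.54±0.08) were among the higher genes.

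Cd274 followed the interferon gamma list over the libraries: r = 0.87 over all 14 (permutation p = 5.0e-05, Spearman rho = 0.78) and r = 0.80 over the 11 day 7 libraries (p = 0.00289, rho = 0.62), with 0.66 when the 2 farthest libraries were left out and 0.82 after centring each group. With the T cell list r was 0.78 over 14 libraries and 0.73 over the 11 day 7 libraries (permutation p = 0.00995). Without the 2 farthest libraries these T cell values were 0.54 and 0.68.

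A hypothesis is that Cd274 in these tumours is set mainly by interferon signalling, and that siRNA lowers it further: with the interferon gamma list as covariate the siPD-L1 minus siNeg difference was -0.33. PD-L1 protein and transcript measured in sorted tumour cells soon after injection would test it. A second hypothesis is that the polymer with paclitaxel lowers the secretory and antioxidant programmes of the tumour cells and not only their stromal share: with the fibroblast covariate the secretory list kept adjusted p = 0.000491 and the Nrf2 list adjusted p = 0.00485 with an estimated correlation, while the median over the genes called lower went from -0.94 to -0.74. Both lists also fell in each siRNA group against day 0 (adjusted p = 0.00438 to 0.0124 with an estimated correlation), where the fibroblast means of the day 0 libraries (3.03 to 3.25) lie within those of the treated libraries (2.58 to 4.06). The Nrf2 list was also lower with D5W than at day 0 (7 of 20 fell, 14 below 0; adjusted p = 0.278 with an estimated correlation), so part of its fall against day 0 need not come from the treatment. Of the secretory list 4 of 26 genes fell and 2 rose with D5W against day 0 (adjusted p = 0.781 with an estimated correlation). Those that fell include Sec61b (-0.69±0.13) and Sec61g (-0.80±0.17), so their fall against day 0 need not come from the treatment either. Comparisons with day 0 also carry the trend with transcript GC content and length, and no values with it removed are given here for these lists. The lists were picked after the pattern was seen, so their p-values do not count as a separate test of it. The injections of 2E' and of 2E'/PTX with single-cell sequencing would test it. A last hypothesis is that the immediate early genes follow tumour collection, where a gap of 1.22 log2 CPM separates the days; day 0 and day 7 tumours collected in the same session would test it.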
